A study of Mus musculus with 10 samples.

How the data were processed

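Whole blood RNA of 10 mice was measured on 10 arrays, 5 from mice given MWCNT and 5 from mice given vehicle, and groups and replicate numbers were taken from the labels. Per the labels' protocols, the authors extracted RNA with a PAXgene blood kit, removed ribosomal RNA, amplified the remainder by random priming along the whole transcript, labelled it with Cy3 and hybridised it to an Arraystar mouse lncRNA array. Replicates were separate mice. Both scanner values and a deposited table were used. The scanner files hold, per the file headers, the intensity of each spot as Agilent Feature Extraction gave it, with the background subtracted and spatial trends removed, the median pixel intensity of spot and surroundings, and flags for outlier, saturated and well above background spots, with nothing adjusted between arrays. The authors' deposited table holds log2 values, and its normalization is not given in the sources used here. Its column medians were all 4.17 when rounded, and its columns correlated with the scanner values at 0.988 to 1.00, from which the log2 scale and direction were taken. Its values differed from quantile-normalized scanner values by a median of 0.0018 to 0.0072 log2 units per array, so results from it and from quantile normalization are not independent alternatives. It held 60819 of the probes analysed.

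Each array had 62939 spots. Control spots, 15 negative probes and spots marked as outliers were left out, no spot was saturated, and spots of one probe were averaged, which left 60915 probes. The processed signal was put on the log2 scale and the 75th percentile of each array was subtracted. Because 47.1% of probes were well above background on an average array, the percentile was taken over the 23404 probes well above background on all arrays. This scaling sets only the 75th percentile of those probes equal between arrays, so every value is relative to that percentile. A probe was tested if it was well above background on at least 5 of the 10 arrays, whatever their group.

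Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Log2 fold changes are MWCNT minus control. Levels per mouse were compared with exact permutation tests over all assignments of the mice to groups, the smallest possible p being 0.00794 for 5 against 5 and 0.0179 for 3 against 5, and shares of probes with Fisher's exact test. Scan run and array position in the file headers placed 8 arrays on one slide (slide 1) and 2 on another (slide 2). The slide was then fitted as a fixed block, in which only slide 1 informs the exposure estimate and slide 2 enters only the residual variance. The step was tested on simulated data for 5 MWCNT against 5 control arrays over 27845 probes, with noise independent between arrays. With 1 group term it recovered 2% of 50 probes changed 1.5-fold, 30% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold, with 8 false among 122 calls. With the slide block it recovered 4%, 34%, 84% and 96%, with 8 false among 117 calls. Independent noise leaves out a shift shared by the arrays of slide 2, so these shares do not give the power in the real data.

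Gene names came from RefSeq accessions in the files, all 15 of which matched a RefSeq gene table of assembly GRCm38.p6, used for names only. Probes of Gapdh, Ppia and Rpl13a, which have many near-identical processed copies in the genome, and of G6pd2, a copy of another gene, may share signal with those copies. The rule for named genes, fixed before the data were examined, took every called gene and, where fewer than 20 were called, the 10 named genes with higher and the 10 with lower means of the smallest unadjusted p. It named Tfrc and Hsp90ab1 among the higher and 10 of the 12 lower genes; the remaining pair, Gusb and Gk, is drawn because the whole set is plotted. The rule also asked for fixed blood markers, which carry no name in the files and are not reported. A probe annotation was not used here, so tests of the 27 fixed gene lists, their level per mouse, an erythroid covariate, averages over the probes of a gene and the comparison of coding with lncRNA probes were not run, except for the probes with lincRNA in their own names, a class chosen after the names were seen. Control probes of Gapdh and Pgk1 whose names end in 3 and 5 were taken as lying near the 3' and 5' ends of the transcript, which the files do not state.

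Alternatives fixed before the data were examined were quantile, median and cyclic loess normalization, the 75th percentile over all probes, normexp background correction with an offset of 50, the deposited values, no filter, a filter on all 10 arrays, the slide and the replicate number as blocks, array weights, a trended robust variance, an adjusted p of 0.1, an unadjusted p under 0.05 with a 2-fold minimum in place of the adjusted threshold, and each array left out in turn. The mean spot signal planned for normexp was replaced by the median spot signal. Slide 1 alone, and most alternatives for the lincRNA-named probes, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.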

Results

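Whole blood RNA was profiled in 10 female C57BL/6 mice aged 3 months. In 5 of them the blood was collected 56 days after multi-walled carbon nanotubes (MWCNT), concentric cylinders of graphene-like carbon, had been given at 40 µg by pharyngeal aspiration, in which a liquid placed at the back of the throat is drawn into the lung. The other 5 mice received the vehicle and served as controls. Each mouse was measured on 1 array of a 1-colour Agilent design that carries probes for messenger RNA and for long non-coding RNA (lncRNA). Of 60915 probes, 47.1% were well above background on an average array, and the 28010 that were so on at least 5 of the 10 arrays were tested. Only 15 reference genes and 1836 probes with lincRNA (long intergenic non-coding RNA) in their own names could be placed, because the files do not pair the other probes with genes.

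The share of probes well above background, the measure of signal over background on these arrays, was 45.1% ± 2.23 (SD, n = 5) in controls and 49.2% ± 7.23 (SD, n = 5) after MWCNT. The difference of 4.04 percentage points was within the spread between arrays (2-sided exact permutation p = 0.333, 252 assignments). The spread in the MWCNT group came from replicate 4, at 55.3%, and replicate 5, at 58.5%. Those 2 arrays were scanned apart from the other 8, as a slide without any control, called slide 2 here. The 252 assignments ignored slide, so their p-value does not measure the spread between mice alone. On slide 1, which held all 5 controls and MWCNT replicates 1 to 3, the MWCNT share was 44.0% ± 1.39 (SD, n = 3), or -1.12 points against the controls (exact permutation p = 0.5, 56 assignments).

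The comparison of MWCNT with control asked which blood transcripts differed in abundance 56 days after the exposure. Of the 15 named reference genes, 14 were measurable in blood and none passed the test between the groups. Actb, which encodes cytoplasmic beta-actin, averaged 4.15 ± 0.20 (SD, n = 5) in controls and 3.68 ± 0.59 (SD, n = 5) after MWCNT, in log2 units relative to the 75th percentile of the array. Its log2 fold change of -0.47 (SE 0.27, limma adjusted p = 0.807) was the largest in size among the 14, and it was -0.05 (SE 0.17) with the slide as a block. Tfrc, the transferrin receptor through which immature red cells take up iron, averaged -1.09 ± 0.20 (SD, n = 5) in controls and -0.89 ± 0.72 (SD, n = 5) after MWCNT. Its log2 fold change was 0.20 (SE 0.30, limma adjusted p = 0.837), with MWCNT replicate 5 far below the other arrays at -2.09. With the slide as a block it was 0.49 (SE 0.31, adjusted p = 1.00), where replicate 5 enters the SE but not the estimate. On slide 1 alone Tfrc was at 0.49 (SE 0.20, limma unadjusted p = 0.0336). That was the smallest unadjusted p of the 14 genes there, and it did not pass the adjusted threshold.

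Of these 14 genes, 12 had lower means after MWCNT and 2, Tfrc and the chaperone gene Hsp90ab1, had higher ones, with limma adjusted p between 0.807 and 0.973. The sign of 9 of the 14 turned when slide was a block. Besides Actb, the housekeeping genes with a lower mean included Tuba1b (alpha-tubulin), with a log2 fold change of -0.32 (SE 0.29), Gapdh (a glycolytic enzyme), with -0.27 (SE 0.27), and Ppia (cyclophilin A), with -0.26 (SE 0.27). With the slide as a block the values of these 3 genes were 0.07, 0.11 and 0.05. Nono, an RNA-binding protein of nuclear paraspeckles, had -0.24 (SE 0.25) and Hprt, an enzyme of purine salvage, -0.23 (SE 0.35), against 0.02 and 0.26 with the block. B2m, the light chain of MHC class I, had -0.22 (SE 0.29) but 0.13 after quantile normalization, 0.11 after cyclic loess, 0.13 in the deposited values and 0.20 with the block. The other 3 genes named by rule had smaller values, at -0.10 for Rpl13a, which encodes a protein of the large ribosomal subunit, -0.09 for G6pd2 and -0.06 for the TATA-binding protein gene Tbp. Hsp90ab1 had 0.21 (SE 0.20), and -0.04 with the block. Ldhal6b, the 15th reference gene, was not well above background on any array.

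**Figure D1:**
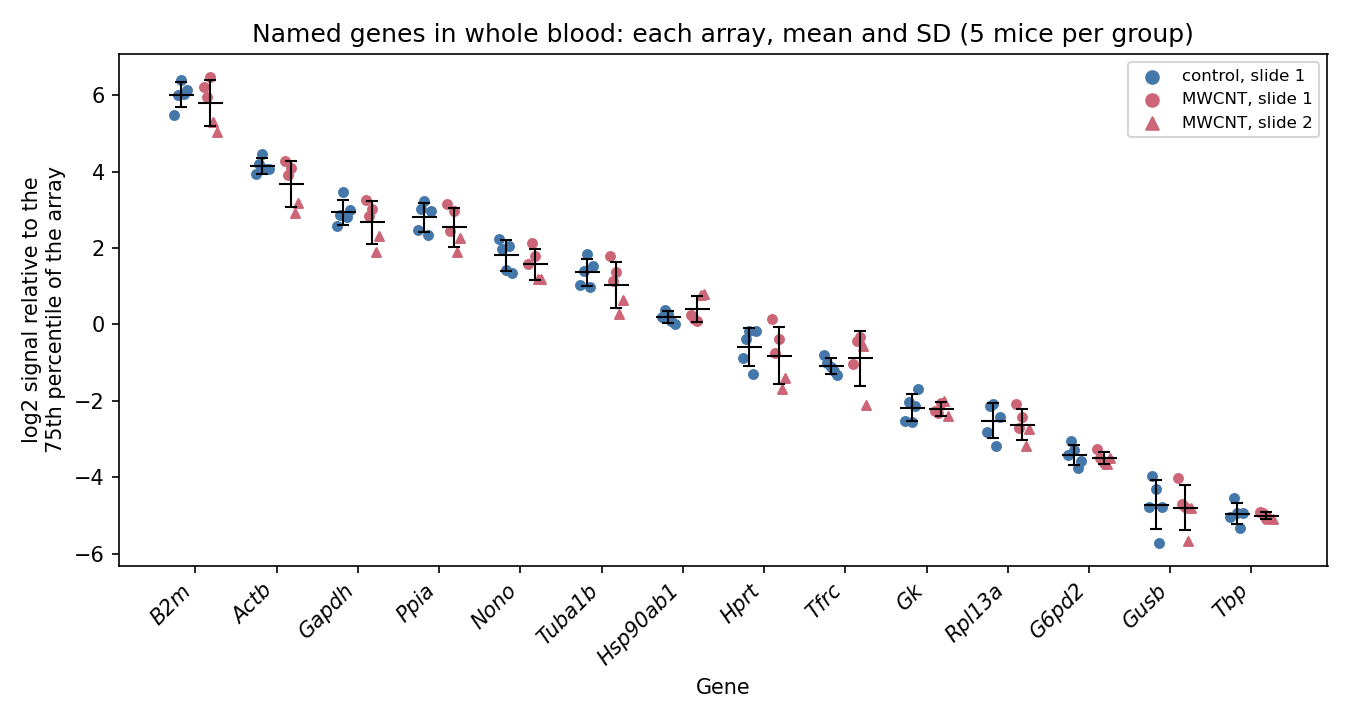
Log2 signal of the 14 measurable reference genes relative to the 75th percentile of each array (vertical axis) for every mouse, by gene (horizontal axis), with black bars for the mean and SD of 5 mice per group. Circles are arrays of slide 1 and triangles the 2 MWCNT arrays of slide 2, which lie lowest for Actb, at 2.93 and 3.18, against a control mean of 4.15; the sign of the group difference turned with the slide as a block for 9 of the 14 genes.

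Averaged over the 14 reference genes, each centred on its own mean, the level was -0.07 ± 0.34 (SD, n = 5) after MWCNT and 0.07 ± 0.22 (SD, n = 5) in controls. The difference of -0.14 log2 units was within the spread between arrays of both slides (2-sided exact permutation p = 0.452). MWCNT replicates 4 and 5 of slide 2 lay at -0.45 and -0.39, against -0.22 to 0.30 on slide 1. On slide 1 alone the difference was 0.10 (exact permutation p = 0.536). For 13 of the 14 genes the 95% interval of the fold change excluded a 2-fold difference in either direction, and for 12 with the slide as a block. Without the block the interval holds for the groups as measured, with any shift of slide 2 included. Of the 27 blood, immune, stress and tissue gene lists fixed before the data were examined, 3 had 1 measured member each, Tfrc among erythroid genes, Hsp90ab1 among stress genes and Rpl13a among ribosomal protein genes. No list reached the 5 members set as the minimum for a test.

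Across all 28010 probes, limma called 0 at an adjusted p of 0.05, and the smallest adjusted p was 0.807. At an unadjusted p under 0.05 there were 815 probes, or 2.91% of those tested, of which 513 had higher and 302 lower means after MWCNT. The nominal share is 5%, but 100 drawn splits of the 10 arrays gave from 60 to 7826 such probes. A share of 2.91% is therefore not evidence of fewer probes than chance gives. With slide as a block limma also called 0 probes (smallest adjusted p = 0.184), with 992 at an unadjusted p under 0.05, 321 higher and 671 lower. On slide 1 alone it called 0 (smallest adjusted p = 0.273), with 976 at an unadjusted p under 0.05. The direction at an unadjusted p under 0.05 depended on the processing. With the percentile taken over probes well above background 62.9% of the 815 were higher, and after cyclic loess 60.7% of 751. The share was 37.7% of 910 with the percentile over all probes and 48.7% of 760 after quantile normalization. It was 45.4% of 862 after median scaling and 49.1% of 751 in the deposited values. After normexp, which changed the background correction and the input signal, it was 30.0% of 913.

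limma with array weights, which gave MWCNT replicates 4 and 5 the lowest weights of 0.174 and 0.310, called 2 probes and had 3642 at an unadjusted p under 0.05. The highest weights were 5.11 for MWCNT replicate 3 and 3.64 for control 2. The weights were estimated from the same data, so the weighted results lean heavily on those arrays. One was ASMM10P045395, with a log2 fold change of 1.07 (SE 0.12, adjusted p = 0.0223) under the weights. Without weights its value was 0.97 (SE 0.19, adjusted p = 0.807), from -1.98 ± 0.15 (SD, n = 5) in controls and -1.01 ± 0.30 (SD, n = 5) after MWCNT, and all 5 MWCNT arrays lay above all 5 controls. The other was ASMM10P046372, at -1.54 (SE 0.19, adjusted p = 0.0264) with weights and -0.99 (adjusted p = 0.807) without. With the slide as a block ASMM10P045395 was at 0.99 (limma adjusted p = 0.356) and ASMM10P046372 at -1.37 (limma adjusted p = 0.184), so neither passed. The lower probe with the smallest unadjusted p without weights was ASMM10P014259, at -1.24 (SE 0.24, limma adjusted p = 0.807). These 3 probes have no gene name in the files and were chosen after their values were seen.

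The precision of 5 arrays per group was enough to exclude a 2-fold difference in either direction for 76.9% of probes and a 4-fold difference for 99.0%, by the 95% interval of each probe, but a 1.5-fold difference for only 22.3%. With the slide as a block these shares were 86.6%, 99.2% and 42.9%. These intervals rest on few arrays. With the block only 3 MWCNT arrays against 5 controls inform the estimate, while the 2 arrays of slide 2 still enter its SE. Where slide is not a block, any shift of slide 2, which held only MWCNT arrays, enters the estimates as well as their spread. Those intervals therefore do not bound the effect of the exposure alone. Within slide 1 the group also followed the position, since the first column of the slide held 4 controls and the second held control 5 and MWCNT replicates 1 to 3.

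The lincRNA-named probes were dimmer than the array as a whole, with 527 of 1836 tested, or 28.7%, against 46.0% of all probes. Of the 1836, 1104 carry humanlincRNA in their names (310 tested), 649 mouselincRNA (190 tested) and 83 a lincRNA exon (27 tested). A series of 923 probes without a gene name was as dim, with 28.1% tested. The other probes mix messenger RNA and lncRNA that could not be told apart, so these comparisons do not set lincRNA against coding RNA. None of the 527 passed the adjusted threshold in limma. At an unadjusted p under 0.05 there were 17, or 3.23%, against 2.90% of the other probes (2-sided Fisher's exact p = 0.601). With the slide as a block there were 31, or 5.88%, against 3.50% of the others (Fisher's exact p = 0.00588), 8 of them higher and 23 lower, and the same number on slide 1 alone (Fisher's exact p = 0.00531). Leaving out single arrays moved the count of 17 to between 10, without MWCNT replicate 4 or control 2, and 56, without MWCNT replicate 1. Probes are not independent of one another, so these p-values over probes are too small. An average of 28.3% ± 1.48 (SD, n = 5) of all lincRNA-named probes was well above background in controls and 32.8% ± 7.32 (SD, n = 5) after MWCNT (exact permutation p = 0.349), and on slide 1 the difference was -0.81 percentage points (exact permutation p = 0.429).

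The arrays did not separate by exposure. The first principal component carried 53.2% of the variance and placed MWCNT replicate 4 at 138 and replicate 5 at 62.9, while the 8 arrays of slide 1 lay between -59.3 and 11.1. The correlation between arrays averaged 0.984 among controls, 0.962 within the MWCNT group and 0.972 between groups. On slide 1 alone it averaged 0.986 within the MWCNT group and 0.985 between groups.

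**Figure D2:**
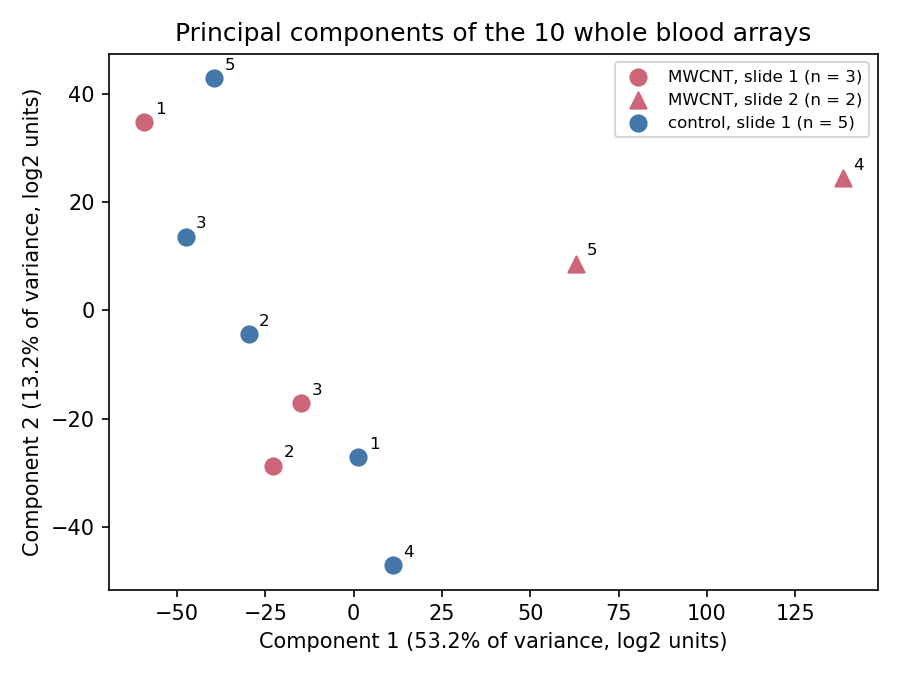
First and second principal components of the 10 arrays over the tested probes (axes in log2 units, 53.2% and 13.2% of the variance), with colour for the group, shape for the slide and the replicate number beside each point. The 2 MWCNT arrays of slide 2 sit at 138 and 62.9 on the first component, and MWCNT replicates 1 to 3 lie between -59.3 and -14.8, against -47.6 to 11.1 for the controls.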

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

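No array stood far enough from the rest of its group to exceed Dixon's critical value of 0.71 in 44 tests of array quality, component and reference gene values, where chance gives about 2.2. MWCNT replicates 4 and 5 lay apart together in several of these measures, and a pair hides each other from that test.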

How the results depend on the processing

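Slide 1 alone, and the alternatives for lincRNA-named probes other than no filter and quantile normalization, were added after seeing the data. At an adjusted p of 0.05 limma called 0 probes under every alternative run except array weights, which called 2 (smallest adjusted p = 0.0223). For the 14 reference genes, 0 of 322 alternative values passed the threshold; signs turned for 9 genes with slide as a block or slide 1 alone, 5 with array weights, 4 without control 2 and up to 2 elsewhere. The 815 probes at an unadjusted p under 0.05 became 1647 with no filter, where more probes are tested, and 3642 with array weights, and 67 of the 815, with no adjusted threshold, were also at least 2-fold. Leaving out 1 array gave 392 to 2645: 2645 without MWCNT 1, 1931 without MWCNT 2, 410 without MWCNT 4, 392 without MWCNT 5, 428 without control 2 and 457 without control 3, with 0 calls each and a smallest adjusted p between 0.454 and 1.00; the cause was not tested. The lincRNA-named count of 17 was 49 with no filter (more probes tested), 31 with slide as a block, 31 on slide 1 alone, 80 with array weights, 10 with normexp and 8 with the filter on all 10 arrays (fewer probes tested). Leaving out 1 array gave 10 to 56 of them: 56 without MWCNT 1, 35 without MWCNT 2, 10 without MWCNT 4 or control 2, and 11 without MWCNT 5 or control 3; the cause was not tested. On slide 1 alone, which leaves out the 2 arrays of slide 2, the reference gene mean differed by 0.10 between MWCNT and control. There the correlation within the MWCNT group was 0.986 and the difference in probes well above background -1.12 points. The replicate block gave 0 calls and 889 probes at an unadjusted p under 0.05. Deviations of mice with the same number correlated at -0.45, 0.08, 0.29, 0.33 and -0.20, and 2 of 5 matched their own number best, so the numbers were not taken as pairs. Signal over background limits the 22730 probes that were well above background on no array, about which nothing can be said.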

Other observations

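Tests chosen only after the result was seen were the comparison of slide 2 with other trios of arrays and the splits of all 10 arrays for probe counts by p. The splits of the 10 arrays for probes well above background in only the MWCNT or only the control group were set beforehand. The test of the lincRNA-named probes was chosen after their excess was seen, but before its splits were counted.

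The second slide separated arrays more than the exposure did. Within the MWCNT group, limma called 7558 of 28009 probes between the 2 arrays of slide 2 and the 3 of slide 1, 3333 higher and 4225 lower on slide 2. The direction depended on the processing, with 3560 higher and 2181 lower after quantile normalization, 3335 and 1724 after cyclic loess, and 3476 and 2132 in the deposited values. After normexp, which changed the background correction and the input signal, 3042 were higher and 10787 lower. Among the reference genes Actb was lower on slide 2 by a log2 value of -1.04 (adjusted p = 0.027), B2m by -1.04 (adjusted p = 0.0302), Hprt by -1.21 (adjusted p = 0.0342), Gapdh by -0.94 (adjusted p = 0.0363) and Tuba1b by -0.97 (adjusted p = 0.0418), but most of these calls ended under other scalings, some with the fold nearly as large. Hsp90ab1 went the other way, at 0.63 (adjusted p = 0.0528), 0.72 after quantile normalization (adjusted p = 0.0464), 0.85 after cyclic loess (adjusted p = 0.0327), 0.61 after normexp (adjusted p = 0.0146) and 0.58 in the deposited values (adjusted p = 0.074). After quantile normalization and in the deposited values only Hprt of those 5 genes passed, at -1.20 (adjusted p = 0.037) and -1.36 (adjusted p = 0.034), while Tuba1b was at -0.91 in both (adjusted p = 0.054 and 0.055), Gapdh at -0.73 and -0.92, Actb at -0.64 in both and B2m at -0.22 and -0.23. After cyclic loess none of the 5 passed, with Actb at -0.49, Gapdh at -0.48, B2m at -0.31 and Hprt at -1.08 (adjusted p = 0.054), and after normexp all 5 did. Negative probes read 40.5 and 42.2 on slide 2 against 62 to 72 on slide 1, and the 75th percentile of the signal was 1781 and 1809 against 1079 to 1344.

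Brightness or compression of slide 2 was not the whole cause of that separation, since quantile normalization, which removes any distortion that keeps the order of probes, still gave 5741 calls, or 76.0% of that number. The test of an exposure effect shared with MWCNT replicates 1 to 3 gave no evidence for one and did not exclude it: the change from controls on slide 2 correlated with theirs at -0.22 across probes, which are not independent, and 45 of 56 trios of slide 1 arrays reached as high a value, within a range of -0.45 to 0.51. RNA integrity stayed open: 1 of 4 differences between the 3 and 5 probes of Gapdh and Pgk1 lay outside the range of slide 1, and random priming weakens the measure. The Gapdh differences, 0.92 and 1.25, lay inside it. The value outside was Pgk1 on MWCNT replicate 5, at 8.39. The Pgk1 5 probe was at or near the floor, and on MWCNT replicates 1 to 3 and control 3 it equalled the undetected Ldhal6b. The Pgk1 difference thus partly follows each array's floor and cannot decide on integrity. A difference in hybridisation or handling of the slide may remain, as may a trait of those 2 mice or a response to MWCNT, and these cannot be told apart because slide 2 held no control.

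Chance could not be excluded for the group comparison. Of 100 drawn splits of the 10 arrays, 51 gave at least the 815 probes at an unadjusted p under 0.05 (highest other 7826), and all 100 gave at least the 0 calls, as any split must (highest other 2742). Splits that kept the slide 2 arrays together had a median of 1673 such probes and those that parted them 307, so the counts follow the slide structure. The real grouping also keeps them together, and its 815 lay below the median of 1673. The 51 of 100 thus mixes unlike splits and does not place the 815 among its like. On slide 1, 27 of 56 splits gave at least the 976 probes found (highest other 7791). One probe was well above background on every array of the MWCNT group and on none of the controls, and 81 of 126 splits gave as many or more (highest other 100). On slide 1 alone there was 1 such probe, against 30 on every control and on none of the MWCNT arrays, and 16 of 56 splits gave as many in all (highest other 183).

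The excess of lincRNA-named probes on slide 1, 2.44 percentage points over the other probes, was reached by 9 of the 56 splits of its arrays, the highest other being 3.60. Chance could not be excluded for it, although Fisher's exact test over probes gave p = 0.00531. No biological explanation was tested.

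The 8 arrays of slide 1 spread along one component with 40.4% of their variance, which did not follow the exposure (MWCNT 5.82 ± 40.6, SD, n = 3; control -3.49 ± 42.5, SD, n = 5; exact permutation p = 0.768). Of 17 relations computed, 5 passed Benjamini-Hochberg adjustment. Hprt rose along it with Pearson's r of 0.95 (exact permutation p = 0.000322, adjusted 0.00548) and Spearman's rho of 0.98 (exact permutation p = 0.000397), and r was 0.90 without the 2 farthest arrays and 0.94 after quantile normalization. Nono went the other way, with r of -0.86 (exact permutation p = 0.0102, adjusted 0.0395), rho of -0.83 (exact permutation p = 0.0154) and r of -0.93 without those arrays. Tuba1b also passed, with r of 0.92 (exact permutation p = 0.00241, adjusted 0.0204), rho of 0.93 (exact permutation p = 0.00223) and 0.86 without those arrays, and Ppia and Rpl13a passed on 8 arrays, with r of 0.86 and 0.84, but not on the 6 left without those arrays, with r of 0.75 and 0.68 (exact permutation p = 0.106 and 0.129). The genes are part of the data the component was made from. A component with 40.4% of the variance must correlate with many probes, and the share over all probes is not given here. These p-values therefore do not show a relation particular to these genes. RNA integrity stayed open: the difference between probes taken as the 3' and 5' ends had r of -0.27 and rho of -0.14 for Gapdh (exact permutation p = 0.505 and 0.752) but r of 0.75 and rho of 0.76 for Pgk1 (exact permutation p = 0.0392 and 0.0368, adjusted 0.0923 for r). A Pgk1 5 probe at or near the floor, random priming and 8 arrays keep these values from deciding, although a permutation p of 0.05 or more for Gapdh had been set beforehand as the bound against it. No biological explanation other than the exposure was tested.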
